A study of Homo sapiens with 6 samples.

How the data were processed

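Total RNA from 3 samples of HCC-LM3-fLuc cells exposed to Au-SM5-1 and 3 untreated samples was measured on Affymetrix gene arrays, 1 sample per array. Per the labels' protocols, RNA was extracted with TRIzol, labelled with biotin and hybridised by the manufacturer's procedure. The authors deposited 1 table of log2 expression values, summarised per probe set with RMA per the submitters' processing notes, which give no version. RMA combines background correction, quantile normalization and a median-polish summary of the probes. The values ranged from 1.03 to 13.5, and array medians lay between 5.69 and 5.73. Quantile normalization gives arrays nearly equal distributions by construction, so a change shared by most genes would not be seen, and changes of genes near background are compressed. A genome build is not given in the sources used here, so no coordinates are printed. The same treatment text stands on all 6 samples, so each sample's group was taken from its title. Replicate numbers were taken from the titles too.

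The table held 33297 probe sets. A table of platform annotation named 1 gene for 19460 of them and several for 1754, and 12083 were not listed there and stay unnamed. Entrez identifiers matched current RefSeq genes for 19429 of the 19460, and no symbol changed. For 769 genes with more than 1 such probe set, the probe set with the highest mean over the 6 arrays was used, leaving 18417 genes. Detection calls were not used here, so low signals could not be separated from background, and no filter on low signals was applied. The planned comparison of 3-prime and 5-prime control probe sets, a sign of RNA quality, was not analysed here, because no probe set could be recognised as a control by its name. For the same reason the fit over all probe sets kept all 33297.

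Groups were compared gene by gene on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 2.95, two-sided), with Benjamini-Hochberg adjustment over the 18417 genes and a threshold of 0.05. Counts with an absolute log2 change of at least 1 were also taken. The 3 genes in the study's design text were tested by an exact permutation test as well. A set of 28 gene lists, 560 symbols of which 507 were measured, was written before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. By camera 12 of the 28 passed, 6 on each side, and 0 passed with the correlation estimated from the arrays, the smallest adjusted p being 0.153. The lower lists included the 3 genes of the design text, which credits them to the gene chip results. The NADPH oxidase list, also lower, holds NOX1 and DUOX2 of these genes. Neither call is an independent test. The directional fry test, which asks whether a list's genes move on balance one way and not whether they differ from other genes, called 15 lists, 10 of them among the 12; the others were lysosome and autophagy, NF-kB and cytokines, interferon response, hypoxia and glycolysis, and ribosomal proteins.

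Genes were named by a rule set before the data were examined. It took the 3 genes of the design text. It also took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean was at or above the median of all gene means (6.41). From each list it took up to 4 members with the smallest adjusted p. Alternatives set in advance were a replicate block, the mean of a gene's probe sets, all probe sets, a filter at the median level, median centring, a second quantile normalization, a variance trend with robust moderation, array weights, unmoderated statistics, an offset of 16 on the linear scale, and each array left out in turn. Removal of each array's trend on gene span (genomic length in RefSeq, loess span 0.5) was added after the data were seen, as was the second quantile normalization for the lists.

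The gene test was tested on simulated data with 18417 genes, of which 200 were changed in each of 5 runs. It recovered 35.2% of changes of 0.25, 93.1% of changes of 0.5 and 100% of changes of 1 log2 unit, and 5.59% of its calls were false. The simulated noise was normal, with the SD of each gene set to its moderated value, so these rates may not hold for the arrays. Camera made 0 false calls in 20 simulated runs of 28 lists with independent noise. It recovered a shift of -0.13 in the hepatocyte list in 20 of 20. The simulated genes were not correlated. The correlations estimated from the arrays ran from -0.097 for the genes of the design text to 0.32 for fibroblast and stellate markers. The shift was close to the mean log2 change of the hepatocyte list in these arrays (-0.132). These runs therefore do not test the list calls made on the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.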

Results

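Genome-wide mRNA levels were measured in HCC-LM3-fLuc, a human hepatocellular carcinoma cell line. Au-SM5-1 is the antibody SM5-1 conjugated to gold nanoparticles, and 3 samples exposed to it were set beside 3 untreated samples. The exposed cells received 0.1 mg SM5-1 per mL, from 40 µL of a stock of 2.5 mg/mL, and the exposure time is not given in the sources used here. Cells given the antibody alone or gold particles alone were not analysed here. The 6 arrays had median log2 signals between 5.69 and 5.73 and correlated pairwise with r between 0.995 and 0.997 across probe sets, which are not independent replicates. The median within-group SD of a gene was 0.0552 log2 units in the exposed and 0.0655 in the untreated arrays. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical, and the 3 arrays per group limit the precision.

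Exposed and untreated cells were compared to find which transcripts differed after exposure. TXNIP, which encodes a binding partner of thioredoxin, rose the most among the genes singled out, 1.82-fold from 6.82 ± 0.05 to 7.68 ± 0.07 (mean log2 signal ± SD, n = 3). MED10, a subunit of the Mediator complex, rose by 0.68 on the log2 scale (SE 0.04). OTUD6B, INHBA (the activin beta A subunit) and MT2A (a metallothionein) rose by 0.47 each. PSAT1 and ASNS, enzymes of serine and asparagine synthesis, rose by 0.43 and 0.37, and WEE1, a kinase that inhibits CDK1, rose by 0.37. NEDD1, PTBP2, TERF1 and LRRFIP1 completed the 12 rises, with log2 changes of 0.37, 0.47, 0.38 and 0.50. Other probe sets of MT2A gave smaller log2 changes of 0.25 and 0.225, and those of WEE1 gave 0.39 and 0.016, none of which passed over all probe sets.

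The falls were more numerous. TMEM45A fell 1.76-fold, from 7.22 ± 0.05 to 6.40 ± 0.04 (SD, n = 3), and TM4SF4 and TM4SF20, which encode related four-span membrane proteins, fell by 0.81 and 0.69 on the log2 scale. LGALS2 (galectin-2) fell by 0.77, the chemokine gene CCL20 fell by 0.67, and the serpin gene SERPINB3 fell by 0.62. H4C8, one of the histone H4 genes, fell by 0.75, and ASB4 and CEMIP fell by 0.59 and 0.58. NOX1, DUOX2 and DUOXA2, described with the oxidases, completed the 12 falls. Copies of the H4 and serpin families are close in sequence, so probes may be shared between copies. This was not tested, and it leaves the values of H4C8 and SERPINB3 uncertain.

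Of 18417 genes tested, 354 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 79 that rose and 275 that fell. An absolute log2 change of 0.5 was reached by 32 of them, 2 rises and 30 falls. No gene passed with an absolute log2 change of at least 1, against 3204 genes at an unadjusted p under 0.05 and none at that size in any other setting tried. The groups did not overlap for all 354 genes, and for 25.1% of all genes, where chance gives 10% on average over the possible splits. Genes on the same arrays are not independent, so a single split can lie far from that average. The excess was not tested. With any 1 of the 6 arrays left out, between 21 and 65 genes passed. Each of these fits has fewer samples, so a lost call need not mean that a change rests on 1 array. Of the 354 genes, 17 passed in each of these 6 fits and 276 in none. The 17 included TXNIP, MED10, TMEM45A, NOX1, TM4SF4, LGALS2, TM4SF20, SERPINB3, DUOXA2 and DUOX2, and the 276 included LRRFIP1, PTBP2, TERF1 and ASNS. CCL20 passed in 4 of the 6 fits, and CEMIP, INHBA and MT2A in 3. NEDD1, OTUD6B, PSAT1 and WEE1 passed in 2, and ASB4 and H4C8 in 1. The count was 1637 when only genes at or above the median level were tested, 1739 with a variance trend, 985 with damped low signals, 170 without variance moderation and 65 over all probe sets. With the replicate number as a block, which leaves fewer residual degrees of freedom, 0 genes passed. The smallest limma adjusted p was then 0.065. For LRRFIP1, none of its other 9 probe sets passed, and the mean of its probe sets gave a log2 change of 0.20 with a limma adjusted p of 0.0968.

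**Figure D1:**
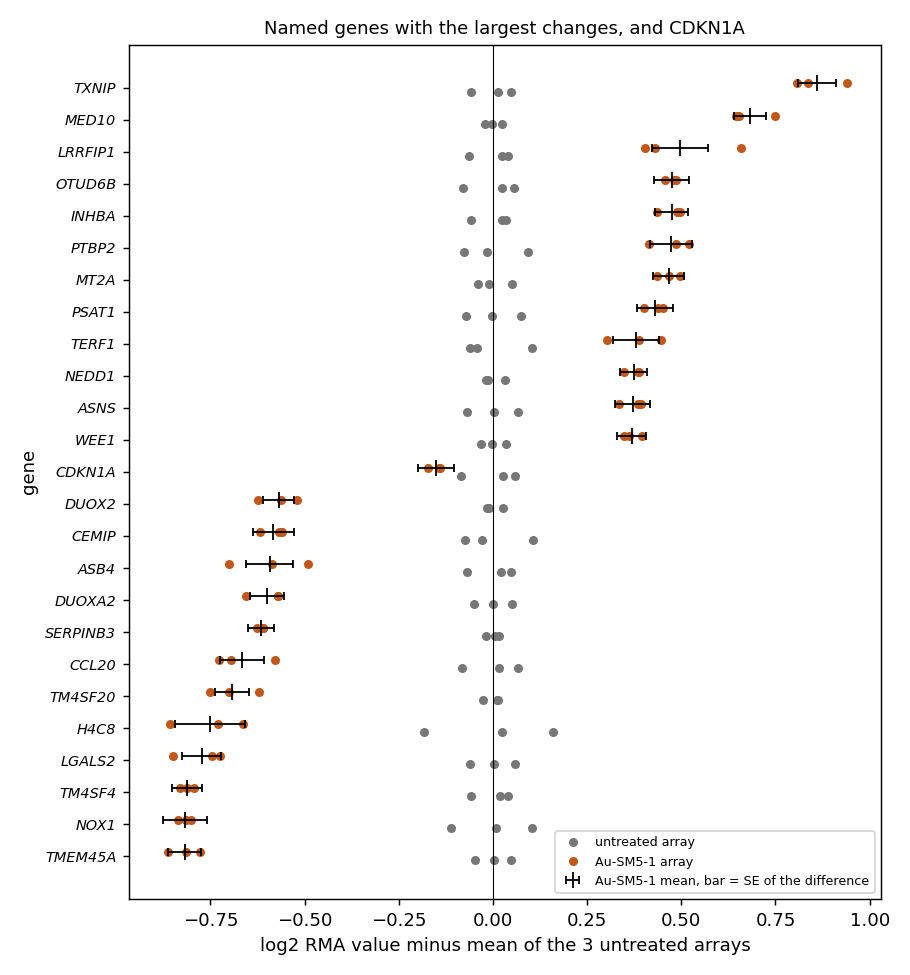
Log2 RMA value of each array minus the mean of the 3 untreated arrays (horizontal axis) for the 12 largest rises, the 12 largest falls and CDKN1A, with untreated arrays in grey, exposed arrays in orange, and a tick at the exposed mean with a bar for the standard error of the difference. The exposed mean lies at 0.86 for TXNIP, -0.82 for NOX1 and -0.15 for CDKN1A, and no exposed array overlaps the untreated arrays of its gene.

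The study's design text names p21 (CDKN1A) as raised and DUOX2 and NOX1 as lowered by Au-SM5-1. NOX1, the catalytic subunit of a superoxide-producing NADPH oxidase, fell by 43.3%, from 6.92 ± 0.11 to 6.10 ± 0.02 (mean log2 signal ± SD, n = 3; probe set 8173979). DUOX2, a dual oxidase that makes hydrogen peroxide, fell by 32.6%, from 8.86 ± 0.02 to 8.29 ± 0.05 (SD, n = 3; probe set 7988350). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, measured 7.43 ± 0.02 in exposed and 7.58 ± 0.08 in untreated cells (SD, n = 3; probe set 8119088). Its value was thus lower in exposed cells, opposite to the direction in the design text, and the difference did not pass the test.

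NOX1 and DUOX2 had log2 changes of -0.82 (SE 0.06) and -0.57 (SE 0.04), each with a limma adjusted p of 0.00462. With the replicate number as a block their limma adjusted p was 0.065 and 0.0713. CDKN1A had a log2 change of -0.15 (SE 0.05) and a limma adjusted p of 0.165. For CDKN1A this p ranged from 0.0343 to 0.380 over the other settings and was 0.0343 when only genes at or above the median level were tested. All 3 genes passed when adjusted over the list alone, CDKN1A with an adjusted p of 0.0158, and the 3 were lower as a list by camera (adjusted p = 6.73e-05, and 0.153 with an estimated correlation). The design text credits these genes to the gene chip results of the study, so neither is independent evidence of a direction. The 3 exposed and 3 untreated arrays did not overlap for any of the 3 genes, and the two-sided exact permutation p was 0.1 for each, the smallest that 3 against 3 arrays allow.

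Among the NADPH oxidase genes, 4 of 13 measured members fell, none rose, and 9 did not pass. Besides NOX1 and DUOX2 these were DUOXA2, the maturation factor of DUOX2, which fell by 0.60 (SE 0.05), and CYBA, the p22phox subunit, which fell by 0.26 (SE 0.04). Adjusted over the list alone, 4 fell. The list was lower than other genes by camera (adjusted p = 0.00744, and 0.282 with an estimated correlation), and its median log2 change was -0.075. The design text names 2 of the 4 genes. CYBA did not pass when any 1 array was left out, while its log2 change stayed between -0.27 and -0.24 in these smaller fits.

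Of 20 oxidative phosphorylation genes, 2 fell and 18 did not pass, and of 19 antioxidant enzyme genes, 2 fell and 17 did not pass. Among the first, 19 had values below 0, and COX6C (cytochrome c oxidase) and ATP5F1A (ATP synthase) fell by 0.30 and 0.26 on the log2 scale. COX4I1 and NDUFA9 had log2 changes of -0.24 and -0.22 and did not pass. SOD1 (superoxide dismutase) and GPX1 (glutathione peroxidase) fell by 0.27 and 0.25, a second probe set of GPX1 gave -0.095 and did not pass, and SOD2 had a log2 change of -0.19 that did not pass. Adjusted over the list alone, 10 respiratory and 8 antioxidant genes fell. The median log2 changes were -0.134 and -0.089. By camera the adjusted p was 2.49e-05 for oxidative phosphorylation (0.174 as an adjusted p with an estimated correlation) and 6.73e-05 for antioxidant enzymes (adjusted p = 0.153 with an estimated correlation). None of COX6C, ATP5F1A, SOD1 and GPX1 passed with any 1 array left out.

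In the unfolded protein and integrated stress response list, 3 of 24 genes rose: PSAT1, ASNS and DNAJB9, an endoplasmic reticulum co-chaperone with a log2 change of 0.22 (SE 0.04). The other 21 did not pass, and ATF3 had a log2 change of 0.26. Among 16 heat shock genes HSPA4L rose by 0.29 (SE 0.04), and HSPH1 and HSP90AA1 had log2 changes of 0.14 and 0.15 that did not pass. Among 11 metallothionein-list genes MT2A rose by 0.47 and MT1X fell by 0.31, and 10 of the 11 had values above 0. No NRF2 target of 18 measured passed, and HMOX1 (haem oxygenase 1) had a log2 change of 0.17 with a limma adjusted p of 0.119.

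By camera these 4 lists were higher than other genes. The adjusted p was 0.00359 for the unfolded protein list (0.282 as an adjusted p with an estimated correlation), with a median log2 change of 0.032. It was 0.0012 for heat shock proteins, 0.00706 for metallothioneins and 0.00955 for NRF2 targets, with medians of 0.048, 0.133 and 0.028 and an adjusted p of 0.153 with an estimated correlation for each. Adjusted over the list alone, 5 unfolded protein genes, 2 heat shock genes and 2 metallothionein genes rose, 1 metallothionein gene fell, and no NRF2 target passed. The metallothionein p became 0.422 when only genes at or above the median level were tested, and the NRF2 p became 0.0512 without untreated replicate 1. The metallothionein genes are near-identical copies, so probes may be shared between them. Neither ASNS, DNAJB9, HSPA4L nor MT1X passed with any 1 array left out, while MT2A passed in 3 of the 6 such fits and PSAT1 in 2.

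Of 27 genes of the G1/S transition and DNA replication, CDC6, a replication licensing factor, fell by 0.43 (SE 0.04), and TYMS (thymidylate synthase) and UNG (uracil-DNA glycosylase) fell by 0.23 each, while none rose. PCNA had a log2 change of -0.19 that did not pass. None of 27 G2/M and mitosis genes passed, although 19 had values above 0, with HMMR at 0.32 and BIRC5 at -0.25. None of 15 CDK inhibitors, D cyclins and partners passed, CDKN1B standing at -0.22 and CCND1 at -0.14. None of 24 p53 targets passed, with TP53INP1 at -0.21 and POLH at 0.14.

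The G1/S list was lower by camera (adjusted p = 0.00744, and 0.153 with an estimated correlation) and the G2/M list higher (adjusted p = 0.00744, and 0.328 with an estimated correlation), with median log2 changes of -0.068 and 0.045. Adjusted over the list alone, 5 G1/S genes fell, and 1 G2/M gene rose and 1 fell. The camera adjusted p was 0.355 for CDK inhibitors and D cyclins and 0.912 for p53 targets, and no member of either passed over the list alone. The p53 list had a median of -0.012 while camera ranked it on the higher side. The G1/S p was 0.13 without untreated replicate 3 and 0.0555 when only genes at or above the median level were tested, and the G2/M p was 0.0962 with fry. TYMS and UNG did not pass with any 1 array left out, and CDC6 passed in 4 of the 6 such fits.

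In the hepatocyte list 6 of 24 measured members fell and 18 did not pass. FGB and FGA (fibrinogen chains) fell by 0.39 and 0.32 on the log2 scale, TF (transferrin) fell by 0.48 and APOH (apolipoprotein H) fell by 0.28, with SEs from 0.04 to 0.06. RBP4 and AMBP fell by 0.24 and 0.27, and 7 members fell when adjusted over the list alone. The list was lower by camera (adjusted p = 0.000378, and 0.153 with an estimated correlation), with a median log2 change of -0.111. In the list of integrins and adhesion genes, CCN2 (connective tissue growth factor) rose by 0.30, alone of 21 measured members and alone when adjusted over the list alone. That list was higher by camera (adjusted p = 0.0199, and 0.319 with an estimated correlation), with a median of 0.022. Its camera p became 0.0624 without Au-SM5-1 replicate 2 and 0.0867 without untreated replicate 3, and fry gave 0.0679. APOH, RBP4, AMBP and CCN2 did not pass with any 1 array left out, FGA and TF passed in 1 of the 6 such fits and FGB in 3.

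**Figure D2:**
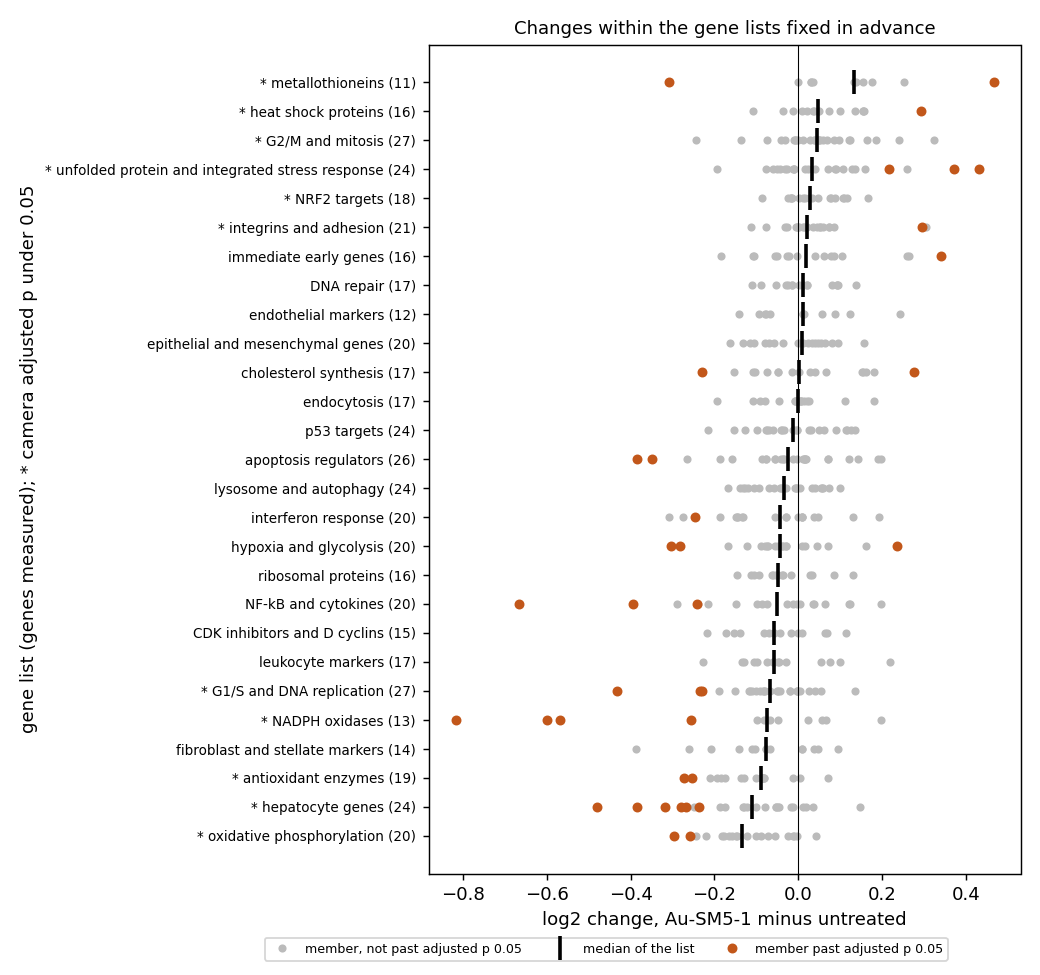
Log2 change (exposed minus untreated, horizontal axis) of each measured member of the gene lists other than the 3 study genes, with members past the adjusted p threshold in orange, the others in grey, a bar at the median of each list and an asterisk on lists past the camera threshold. Medians run from -0.134 for oxidative phosphorylation to 0.133 for metallothioneins.

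Of 20 NF-kB and cytokine genes, CCL20, NFKBIA (the inhibitor of NF-kB alpha) and CXCL5 fell by 0.67, 0.39 and 0.24. OAS1 fell by 0.25 among 20 interferon response genes, and EGR1 rose by 0.34 among 16 immediate early genes. Of 26 apoptosis regulators, TNFSF10 (the death ligand TRAIL) and BAD fell by 0.38 and 0.35. HMGCS1 rose by 0.28 and EBP fell by 0.23 among 17 cholesterol synthesis genes. Of 20 hypoxia and glycolysis genes PDK1, a kinase that inhibits pyruvate dehydrogenase, rose by 0.24, and ALDOC and P4HA1 fell by 0.30 and 0.28.

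The camera adjusted p was 0.0811 for NF-kB and cytokines, 0.112 for interferon response, 0.102 for immediate early genes, 0.544 for apoptosis regulators, 0.332 for cholesterol synthesis and 0.201 for hypoxia and glycolysis. Adjusted over the list alone, the rises and falls numbered 1 and 5, 0 and 3, 3 and 0, 1 and 5, 3 and 2, and 1 and 3 in that order. Directional fry called NF-kB and cytokines (adjusted p = 0.0133), interferon response (0.0103) and hypoxia and glycolysis (0.0409). By camera the NF-kB list passed without Au-SM5-1 replicate 1 (0.0137), and the interferon and immediate early lists passed without untreated replicate 1 (0.0305 and 0.0343). NFKBIA passed in 2 of the 6 fits with 1 array left out, and CXCL5, OAS1, EGR1, TNFSF10, BAD, HMGCS1, EBP, PDK1, ALDOC and P4HA1 in none.

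No member passed among 24 lysosome and autophagy, 17 endocytosis, 17 DNA repair, 16 ribosomal protein or 20 epithelial and mesenchymal genes. GLA had a log2 change of -0.13, AP2M1 -0.19, XRCC5 0.14, RPS4X -0.15 and CDH1 -0.11. Their camera adjusted p was 0.37, 0.912, 0.306, 0.332 and 0.912. Directional fry called the lysosome and autophagy list (adjusted p = 0.036) and the ribosomal protein list (adjusted p = 0.0133), both on the lower side. Markers of other cell types did not pass either, with none of 17 leukocyte, 12 endothelial and 14 fibroblast and stellate markers called and camera adjusted p of 0.641, 0.399 and 0.112. The fibroblast list passed without Au-SM5-1 replicate 1 (0.0317) and without untreated replicate 3 (0.0116). Adjusted over the list alone, 1 endocytosis gene rose and 1 fell, 1 endothelial marker rose, and no member of the other 6 lists passed. The endocytosis list had a mean of -0.010 while camera ranked it on the higher side, and the epithelial and mesenchymal list had a mean of -0.007, a median of 0.009 and the higher side by camera.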

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

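Probe sets that the gene-level comparison left out were tested in a fit over all 33297 probe sets, and some passed the same threshold. Of 1754 probe sets that list several genes, 2 passed (287 at an unadjusted p under 0.05). Both list GSTT2B and GSTT2, hold identical values and had a log2 change of -0.43 with a limma adjusted p of 0.0476. Of 12083 probe sets that the annotation table does not list, 14 passed, 10 that rose and 4 that fell (1588 at an unadjusted p under 0.05). Their log2 changes reached 0.75 and -0.74, and no gene is named for them here.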

How the results depend on the processing

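Of the settings described here, removal of the gene-span trend and, for the lists, the second quantile normalization were chosen after the data were seen. Against 354 genes (79 rises, 275 falls), 1637 genes passed when only genes at or above the median level were tested (491, 1146), 1739 with a variance trend and robust moderation (538, 1201), 985 with the offset of 16 (279, 706), 170 without moderation (40, 130) and 65 over all probe sets (17, 48). The filter and the wider set change the number of tests, and they also change the genes from which the variance moderation is estimated. The cause of the differing counts was not tested. With 1 array left out, 21 to 65 genes passed, 2 to 14 rises and 19 to 51 falls, each fit having fewer samples. No gene reached an absolute log2 change of 1 in any setting. The mean of probe sets, both normalizations, array weights and removal of the span trend gave 325 to 457 genes. All 354 genes kept their direction in every setting that measured them, the filter measuring 287. Much of this was fixed in advance. Groups that do not overlap cannot change direction when 1 array is left out. The block, the filter, the fit over all probe sets, the variance trend and the unmoderated fit keep the log2 changes of the main fit. In these settings the kept direction is no check of the calls.

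With the replicate number as a block 0 genes passed in limma, 0 rises and 0 falls, with 2971 at an unadjusted p under 0.05. DUOX2 (-0.57, adjusted p = 0.0713) and NOX1 (-0.82, adjusted p = 0.065) lost their calls, and 12 lists passed. The block leaves fewer residual degrees of freedom. Deviations from group means correlated at -0.03, 0.05 and 0.07 between same-numbered arrays, and not every array correlated best with its own number. These values show no clear pairing, but with so few arrays they cannot exclude a shared culture or batch. CDKN1A (-0.15) passed with the filter at the median level (0.0343); over the settings its adjusted p ran to 0.380. Leaving out 1 array gave -0.20 to -0.12 for CDKN1A, -0.59 to -0.54 for DUOX2 and -0.87 to -0.77 for NOX1.

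Of 28 lists 12 passed, 0 with an estimated correlation, 27 with fry's mixed test, which asks for change in either direction, and 11 to 14 with 1 array left out. The immediate early list passed (0.0288) with the span trend removed. The uncalled p53 list turned with the block (0.989) and fry (0.65), and in 3 of the 6 fits with 1 array left out (adjusted p 0.646 to 0.951). Endocytosis turned with fry (0.623) and in 3 of these 6 fits (0.52 to 0.992). Epithelial and mesenchymal genes turned with the filter (0.702) and fry (0.623) and in 1 of these 6 (0.606 to 0.992), and leukocyte markers turned with the filter (0.227). The cause was not tested. Of the other 120 named genes 49 were called; they kept the call in 427 of 535 values under other settings and in 82 of 294 with 1 array left out. The 71 not called gained one in 148 of 767 values and in 1 of 426 with 1 array left out. None of these values reversed.

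The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 354 genes and the highest other 0; for lists the values were 12 and 2, again with 1 of 10 as large. The split test of gene counts was chosen after the result was seen. The 12 lists include the 3 genes that the design text credits to the gene chip results. Signal over background is unknown without detection calls.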

Other observations

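The genes in this part were chosen after their values were seen, and so were the 4 added lists; the tests of CDKN1A and of the parts of the amino acid list were also chosen after the result was seen. MPC1 and MPC2, the subunits of the mitochondrial pyruvate carrier, fell by 0.26 and 0.40 on the log2 scale, and PDHA1, a subunit of pyruvate dehydrogenase, fell by 0.24, while PDK1 rose by 0.24. Their limma adjusted p was 0.0347, 0.00695, 0.0472 and 0.0379. With 1 array left out, MPC2 passed in 3 of 6 fits and the other genes in none. VIL1 (villin, a protein of gut microvilli) fell by 0.43 and LGR5, a Wnt-pathway receptor, fell by 0.65, each with a limma adjusted p of 0.00695. Their groups did not overlap, which held for every called gene. VIL1 passed in 4 and LGR5 in 5 of the 6 fits with 1 array left out.

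ID1 and ID3, targets of BMP signalling, fell by 0.40 and 0.50, and the pathway inhibitors SMAD6, SMAD7 and BAMBI fell by 0.25, 0.26 and 0.38. GREM1, a secreted BMP antagonist, rose by 0.31 (limma adjusted p = 0.0281). With 1 array left out, ID1 and ID3 passed in 3 of 6 fits, BAMBI in 1, and SMAD6, SMAD7 and GREM1 in none. Of 14 listed BMP and SMAD target genes 5 fell and none rose. An amino acid list held 22 measured genes, 10 synthesis and one-carbon enzymes and 12 amino acid transporters and tRNA synthetases. Among the enzymes PSAT1 and ASNS rose, as did ALDH1L2 by 0.35 and PHGDH by 0.28, and among the others the tRNA synthetase gene YARS1 rose by 0.25. PSAT1 passed in 2 of the 6 fits with 1 array left out and the other genes in none. PSPH, the serine synthesis enzyme that follows PSAT1, had a log2 change of -0.30 (limma adjusted p = 0.0568). PSAT1 and ASNS also stand in the unfolded protein and integrated stress response list.

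A wider rise of amino acid synthesis genes of the ATF4 type remained open. Without the 5 called genes, the other 17 of the list had a median log2 change of 0.080 and a camera p of 0.000367, or 0.0814 with an estimated correlation. The bound set in advance, a median above 0 and a camera p under 0.05, was met. It was set aside because the p with an estimated correlation missed 0.05 and the parts of the list differed. The second reason is weak, because dropping the called genes cut the parts unequally. The split into parts was chosen after the result was seen. Of the 17 genes, the 6 enzymes had a median of 0.013, 3 of them below 0, and a camera p of 0.98. Dropping the called genes had taken out 4 of 10 enzymes, all rises, so a median near 0 is partly built in. All 10 enzymes had a median of 0.176, with 7 above 0 and 3 below. Their camera p was 0.000444, or 0.0312 with an estimated correlation, but it includes the called genes and is no independent support. The 11 transporters and tRNA synthetases had a median of 0.098, 10 of them above 0, and a camera p of 5.9e-06, or 0.0623 with an estimated correlation. A wider fall of BMP target genes remained open: the 9 other genes had a median of -0.065 and a camera p of 0.1. A lower gut epithelial programme remained open as well, since 21 genes had a median of -0.029 and a camera p of 0.131. Fewer cells in S phase may lower replication-dependent histone genes, of which H4C8, H2BC12, H2BC10 and H3C3 fell. H4C8 passed in 1 of 6 fits with 1 array left out, and the others of these in none. The other 53 histone genes had a median of -0.011, with 26 above 0 and 27 below. Their camera p was 0.543, on the higher side, so this explanation stays open. Among them H4C14 and H4C15 held identical means and log2 changes (0.27), so they may not be separate measurements. For all 57 histone genes the median went from -0.015 to -0.004 once the gene-span trend was removed. The camera p was 0.649 before removal, and the value after it was not tested against other genes. The bounds set in advance counted a p of 0.05 or more against the gut and S-phase explanations; that was wrong, because a p that misses the threshold does not show that nothing moved.

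More genes fell than rose, 77.7% of the called genes. Array-wide scaling stays open: the share was 79.3% after median centring and 73.9% after a second quantile normalization, but these moved log2 changes by a median of 0.00497 and 0.01, against a median size of 0.303 among called genes. RMA had already evened out the arrays, so the bound set in advance on this share decides nothing. The tables argue against a gene-span trend between arrays as the whole cause, since 69.2% fell once it was removed, above the bound of 60% set in advance. Genes that fell had a median span of 17.8 kb, genes that rose 41.7 kb and all genes 24.5 kb. An effect of exposure stays open too, and transcript length and RNA quality were not tested.

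The lower values of oxidative phosphorylation and antioxidant genes are not explained by the gene-span trend. The median log2 change of 39 pooled members was -0.101 before and -0.104 after its removal. An effect of exposure and a difference in RNA quality both stay open, the latter not tested.

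CDKN1A was lower in exposed arrays although the design text gives it as raised. Exchanged group labels would raise NOX1 and DUOX2, which instead had log2 changes of -0.817 and -0.569, in the direction of the design text. Variation between arrays alone cannot be told apart from a small fall, since the adjusted p of CDKN1A in limma was 0.165 and its groups did not overlap. Whether other processing lies behind the direction in the design text was not tested.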
